A study of Arabidopsis thaliana with 16 samples.

How the data were processed

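RNA was taken from whole Arabidopsis thaliana seedlings of the Columbia-0 wild type (Col-0) and of a line that carries 35S::FLAG-GR-KAN1. In that line a strong viral promoter drives KANADI1 (KAN1), a transcription factor of the GARP family known for its role on the lower side of the leaf, fused to a FLAG tag and to the hormone-binding part of the glucocorticoid receptor. Such a fusion is held outside the nucleus until a glucocorticoid such as dexamethasone (DEX) is given. Per the labels' protocols, seedlings were 10 days old, had been cold-treated at 4 °C for 3 days and grown at 22 °C in long days, and were treated for 90 min with DEX or with a mock solution of 0.5% ethanol. The shaded seedlings spent the last 45 min of that time under shade, and the others stayed in ambient light (labelled WL). Genotype, treatment and light give 8 groups, each with 2 libraries that the series design calls technical replicates, 16 libraries in all, made with a TruSeq RNA kit per the labels' protocols.

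Reads were checked with FastQC 0.10.1, aligned with TopHat2 2.0.9 to the TAIR10 genome and compared with Cuffdiff, per the submitters' processing notes. The Cuffdiff version, its library normalization and its dispersion setting are not given in the sources used here. One deposited table was used, a Cuffdiff gene differential expression table with 33557 genes in each of the 28 pairs of groups. Its expression values are FPKM per gene and group as the authors' Cuffdiff run estimated them over both libraries of a group, per the file headers. The fold changes are log2 ratios of those FPKM with no pseudocount, per the file headers, and were within 5.45e-05 of the ratio of the deposited FPKM for every finite value. The test statistic is Cuffdiff's own signed score per gene and pair, per the file headers. The deposited p-value has a floor of 5e-05, and the deposited q-value was within 5.26e-07 of a Benjamini-Hochberg adjustment over all 541154 tests of the 28 pairs together, which puts the smallest q at 0.00183. Cuffdiff tested 19046 to 19471 genes per pair.

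The table holds no value per library, so no spread between replicates could be computed here and no error stands beside a group's FPKM. Because the replicates are technical, the deposited p-values and q-values measure the spread between library preparations or sequencing runs as Cuffdiff modelled it, and not the spread between separately grown plants. No read counts are in the table. Low FPKM were searched for steps of whole reads: among 1546 genes under 0.3 FPKM in the groups compared, the fullest bin of the ratio between groups, 0.02 wide on the log2 scale, held 4.92%, so whole reads were not recovered and the depth of each library is unknown. The sum of FPKM per group ranged from 862484 to 951109, which does not measure depth. A locus in the file can span overlapping genes, and the reads could then be split wrongly between them; the kit and the sources used here do not say whether strand was used.

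Groups were taken from the sample titles. Of the 28 pairs, 10 were used: DEX against mock in each genotype and light, shade against WL in each genotype and treatment, and GR-KAN1 against Col-0 under mock in each light. A gene was called when its deposited status was OK and its deposited q was under 0.05, and no new test was fitted on group values. To compare 2 responses, the difference of their log2 fold changes was divided by the root of the summed squared standard errors. Each standard error was the deposited log2 fold change divided by the deposited statistic. A two-sided normal p with Benjamini-Hochberg adjustment followed, called under 0.05; the rule set beforehand allowed this because the Spearman correlation of the absolute statistic with the deposited p was -0.99, stronger than the limit of -0.9. In 4 such difference tests 19012 to 19037 genes entered. Overlaps of calls were set against the number that independent lists would share, with Fisher's exact test (two-sided) across genes, which are not independent replicates. That number is not matched on expression, so an excess over it does not alone show a link between 2 responses. Correlations were computed across genes with at least 1 FPKM in the higher group of both comparisons.

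Lists of genes were fixed by gene identifier before the data were examined. The 19 lists are shade markers, auxin response, auxin synthesis, transport and perception, leaf polarity, brassinosteroid metabolism, gibberellin, cytokinin response, ethylene, abscisic acid, jasmonate and wounding, touch and early stress, heat shock, circadian clock, light signalling, flavonoid and high light, cell wall growth, photosynthesis in leaves, root markers, and meristem and division. Of their 245 entries, 244 were kept, and 1 carried another name in the reference and was dropped. Some genes are in more than 1 list. The shade markers share IAA29 with auxin response, YUC8 and YUC9 with auxin synthesis, transport and perception, and XTH15 with cell wall growth. Counts of such lists are not separate evidence. Names were matched by locus tag to a RefSeq annotation of assembly TAIR10.1, which held 32809 of the genes, and no coordinate printed here was taken from it. Its gene starts and the sequence of that assembly gave the 500 bp upstream of each gene that were searched for a binding motif. For each list the calls were counted over all genes as deposited and again adjusted over the list alone, and the median log2 fold change of members with at least 1 FPKM in the higher group was placed among the medians of 10000 random lists of the same size, drawn from the same expression deciles. This percentile describes these libraries only. Lists for phosphate starvation, iron, sugar starvation, seed storage and a wider set of root genes were drawn up after the data had been looked at and are named as such.

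Genes were named by a rule written beforehand: KAN1; the 6 largest rises and falls among called genes with a symbol and at least 1 FPKM in both groups, for each of the DEX responses of GR-KAN1 (leaving out genes called with DEX in Col-0 in the same light) and for the shade response of mock-treated Col-0; the 3 largest for the control comparisons; up to 4 called members of each list; and the 6 genes with the smallest p in each difference test. Genes named outside this rule are said to be so chosen. Alternatives tried were the adjustment within each comparison, a q of 0.01, an absolute log2 fold change of at least 1, an FPKM minimum of 1 or 5, a normal p from the statistic with and without centring, pseudocounts of 1 and 0.1, the removal of genes called with DEX in Col-0, and, added after the data were seen, a standard error from the deposited p and the removal of organelle genes and genes that are not protein-coding. The deposited p cannot fall below its floor, so for genes at the floor a standard error taken from it is only an upper bound. The difference test was tested on simulated data built from the deposited standard errors: a true log2 difference of 2 was recovered for 73% of the changed genes in the WL test of GR-KAN1 against Col-0, 60% in its shade test, 63% in the test of shade against WL within GR-KAN1, and 62% in the test of the shade responses; a difference of 1 was recovered for 11%, 9%, 10% and 6%. Simulated genes with no difference made up 4.5%, 1.4%, 7.6% and 2.9% of the calls, with the test of shade against WL within GR-KAN1 above the nominal 5% (6 genes). The noise was drawn with the standard errors that the test then used, so the simulation cannot check whether these are right. A rank correlation does not check their size either. PSAJ, with log2 -2.09 and a deposited p of 0.0989 with DEX in GR-KAN1 in WL, had a standard error of 0.0174 for its difference from Col-0. The counts of the difference tests rest on such standard errors. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.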

Results

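Gene expression was measured by RNA sequencing in whole seedlings of 8 groups: Col-0 and GR-KAN1, each with mock or DEX treatment, each in ambient light (WL) or shade. Each group had 2 technical replicate libraries, and the values analysed are 1 FPKM per gene and group. A difference is therefore judged by the q that Cuffdiff gave in the authors' deposited table and not by a spread computed here. Between 18213 and 18725 genes reached 1 FPKM in a group. The questions are which transcripts moved when the fusion was induced, whether shade altered that, and how the 2 responses met. Depth is unknown, so a gene that was not called is a gene without a call and not a gene without a change.

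KAN1 itself (AT5G16560, chromosome 5, 5405350 to 5411424 on TAIR10) was looked at first, as a check on the group labels. In the authors' deposited table it stood at 7.26 to 10.3 FPKM in the 4 Col-0 groups and at 153 and 157 FPKM in GR-KAN1 in WL (mock and DEX) and 150 and 199 FPKM in shade. Under mock it was higher in GR-KAN1 than in Col-0 by 4.22 on the log2 scale in WL and 4.37 in shade, both called in the authors' deposited table. Induction acts on the protein, and the log2 change of KAN1 with DEX in GR-KAN1, 0.03 in WL and 0.40 in shade in the authors' deposited table, was not called. The value adds reads of the transgene and of the gene's own locus, which FPKM per gene cannot separate.

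**Figure D1:**
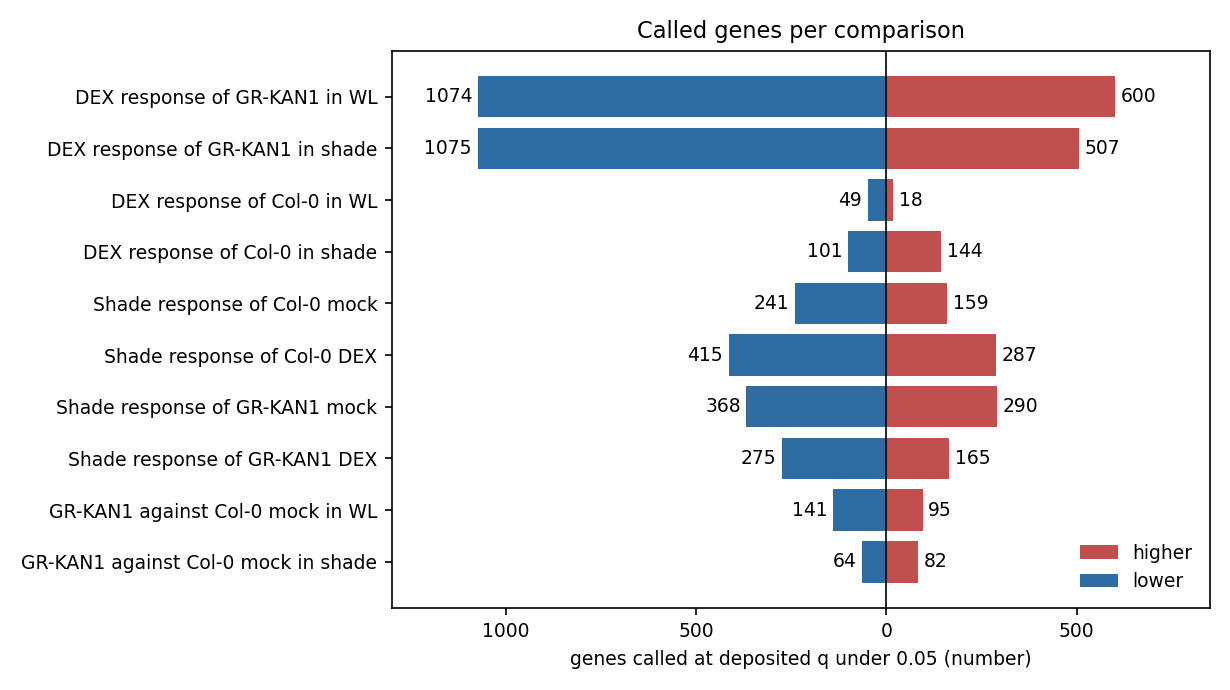
Number of genes called at a deposited q under 0.05 in each of the 10 comparisons, higher to the right of 0 and lower to the left. DEX called 1674 and 1582 genes in GR-KAN1 in WL and in shade, against 67 and 245 in Col-0.

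DEX in GR-KAN1 in WL asked which transcripts move when KAN1 is induced in ambient light. Auxin genes fell together: of 28 tested members of the auxin response list 15 fell, 0 rose and 13 did not pass, and 19 fell when adjusted over the list alone. The median log2 fold change of the list, -1.19, lay below those of all 10000 random lists. The authors' deposited table gave log2 changes of -4.03 for IAA29, -2.17 for IAA14, -2.08 for SAUR15 and -1.94 for GH3.3, which are Aux/IAA, SAUR and GH3 genes known to respond early to auxin. Genes of auxin synthesis, transport and perception followed, with 9 of 18 lower, 0 higher and 9 not passing (adjusted over the list alone, 9 lower and 1 higher; median -0.87). The YUCCA flavin monooxygenases YUC2, YUC6 and YUC8 fell by 4.21, 3.08 and 3.03 on the log2 scale in the authors' deposited table. TAA1, which makes the precursor that YUCCA enzymes convert to auxin, fell from 11.0 to 1.71 FPKM in the authors' deposited table. With pseudocount 1 the log2 fold changes of YUC2, YUC6, YUC8 and IAA29 in the DEX response of GR-KAN1 in WL, whose FPKM with DEX were under 1, were -1.94, -1.39, -1.50 and -2.15. The auxin receptor TIR1, singled out after its values were seen, read 36.4 FPKM under mock and 48.2 FPKM under DEX in the authors' deposited table and was not called.

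In all, 600 genes rose and 1074 fell with DEX in GR-KAN1 in WL, of 19358 tested. Among genes with a symbol and at least 1 FPKM in both groups, and not called with DEX in Col-0 in WL, the largest rises in the authors' deposited table were BHLH137 (AT5G50915; a bHLH transcription factor), from 4.70 to 41.4 FPKM, PHI-1 (log2 3.06), the vacuolar cation exchanger CAX3 (7.85 to 62.7 FPKM), the xyloglucan endotransglucosylase XTR6 (2.94), the pectin methylesterase ATPMEPCRB (2.88) and the peroxidase PER62 (2.52). Within the same limits the largest falls in the authors' deposited table were TPD1 (log2 -4.01), which encodes a secreted protein needed for anther development, MAKR6 (-3.83), the ethylene response factor ERF107 (-3.72; 88.2 to 6.69 FPKM), EDA39 (-3.66), LOL1 (-3.58) and the guard cell potassium channel KAT1 (-3.50).

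Leaf polarity genes were the next group that moved one way in WL. Of 20 tested, 8 fell, 0 rose and 12 did not pass (11 lower adjusted over the list alone; median -0.61). The authors' deposited table gave log2 -4.49 for AS2 and -1.70 and -1.56 for the HD-Zip III genes ATHB8 and REV, which act on the upper side of the leaf, but also -3.18 for KAN3, a relative of KAN1. With pseudocount 1 the log2 fold changes of AS2 and KAN3 in the DEX response of GR-KAN1 in WL were -2.35 and -1.86. Shade markers had 6 of 15 lower, 2 higher and 7 not passing (8 and 3 adjusted over the list alone; median -0.78). Among the 6 are IAA29 and YUC8, already counted with the auxin lists. BEE1 and PAR2 fell by 2.71 and 1.78 on the log2 scale in the authors' deposited table, and ATHB2 and XTH15 rose by 0.90 and 1.37. Of 7 genes of brassinosteroid metabolism, 4 fell and 3 did not pass, and all 7 fell when adjusted over the list alone (median -1.09). ROT3, DWF4, BR6OX2 and CPD fell by 1.52, 1.21, 1.14 and 1.04 on the log2 scale in the authors' deposited table. The gibberellin list had 3 of 12 lower and 1 higher (4 and 4 adjusted over the list alone; median -0.40). GASA6, the biosynthetic gene GA20OX1 and GA2OX6 fell by 2.60, 2.45 and 1.48 on the log2 scale in the authors' deposited table, and GASA1 rose by 0.81. The log2 fold change of GA20OX1 in the DEX response of GR-KAN1 in WL was -1.46 with pseudocount 1.

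Touch and early stress genes rose: 4 of 8 tested were higher, 0 were lower and 4 did not pass in WL (5 higher adjusted over the list alone; median 0.69). TCH4, a xyloglucan endotransglucosylase induced by touch, rose by 2.17 on the log2 scale in the authors' deposited table, and the zinc finger genes ZAT10 and ZAT12 rose by 1.38 and 1.11. The abscisic acid list split, with 5 of 17 lower, 1 higher and 11 not passing (5 and 3 adjusted over the list alone; median -0.00, mean -0.33). Its falls in the authors' deposited table included the receptors PYL6 (log2 -3.04), PYL5 (-1.37) and PYL4 (-1.32) and NCED3 (-2.57), the enzyme that limits abscisic acid synthesis. The log2 fold change of NCED3 in the DEX response of GR-KAN1 in WL was -1.12 with pseudocount 1. PKS1 and PIF7, both known in phytochrome signalling, fell by 1.78 and 1.70 on the log2 scale in the authors' deposited table, and the other 11 tested members of the light signalling list did not pass (2 lower adjusted over the list alone; median -0.16). In the cell wall growth list the expansins EXPA1 and EXPA8 fell (log2 -3.26 and -2.35 in the authors' deposited table) while XTH15 and XTH16 rose (1.37 and 0.94), and 7 of 11 did not pass (3 lower and 2 higher adjusted over the list alone; median -0.30).

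In each of the other lists at most 3 genes rose and at most 2 fell in WL. The medians of the root marker, jasmonate and wounding, clock and photosynthesis lists lay outside the central 95% of random lists. The flavonoid and high light list had 3 of 12 higher and 2 lower (4 and 3 adjusted over the list alone), and its median (0.09) and mean (-0.07) differed in sign. DFR and LDOX, late enzymes of anthocyanin synthesis, fell by 1.25 and 1.11 on the log2 scale in the authors' deposited table. In the jasmonate and wounding list 1 of 13 rose and 1 fell, counts that stayed at 1 and 1 adjusted over the list alone (median 0.30). The cytokinin response list had 1 of 8 higher (1 adjusted over the list alone; median -0.15). The ethylene list had 1 of 6 higher (1 higher and 1 lower adjusted over the list alone; median -0.45). The root marker list also had 1 of 6 higher (1 adjusted over the list alone; median 0.48). In the meristem and division list STM, a homeobox gene of the shoot meristem, fell by 2.15 on the log2 scale in the authors' deposited table, and the other 5 tested did not pass (1 lower adjusted over the list alone; median -0.38). The log2 fold change of STM in the DEX response of GR-KAN1 in WL was -1.23 with pseudocount 1. Cuffdiff called 0 of 6 heat shock, 0 of 11 circadian clock and 0 of 9 leaf photosynthesis genes, with 1, 3 and 0 at an unadjusted deposited p under 0.05. Their counts adjusted over the list alone were 0, and their medians were 0.02, 0.27 and -0.25.

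**Figure D2:**
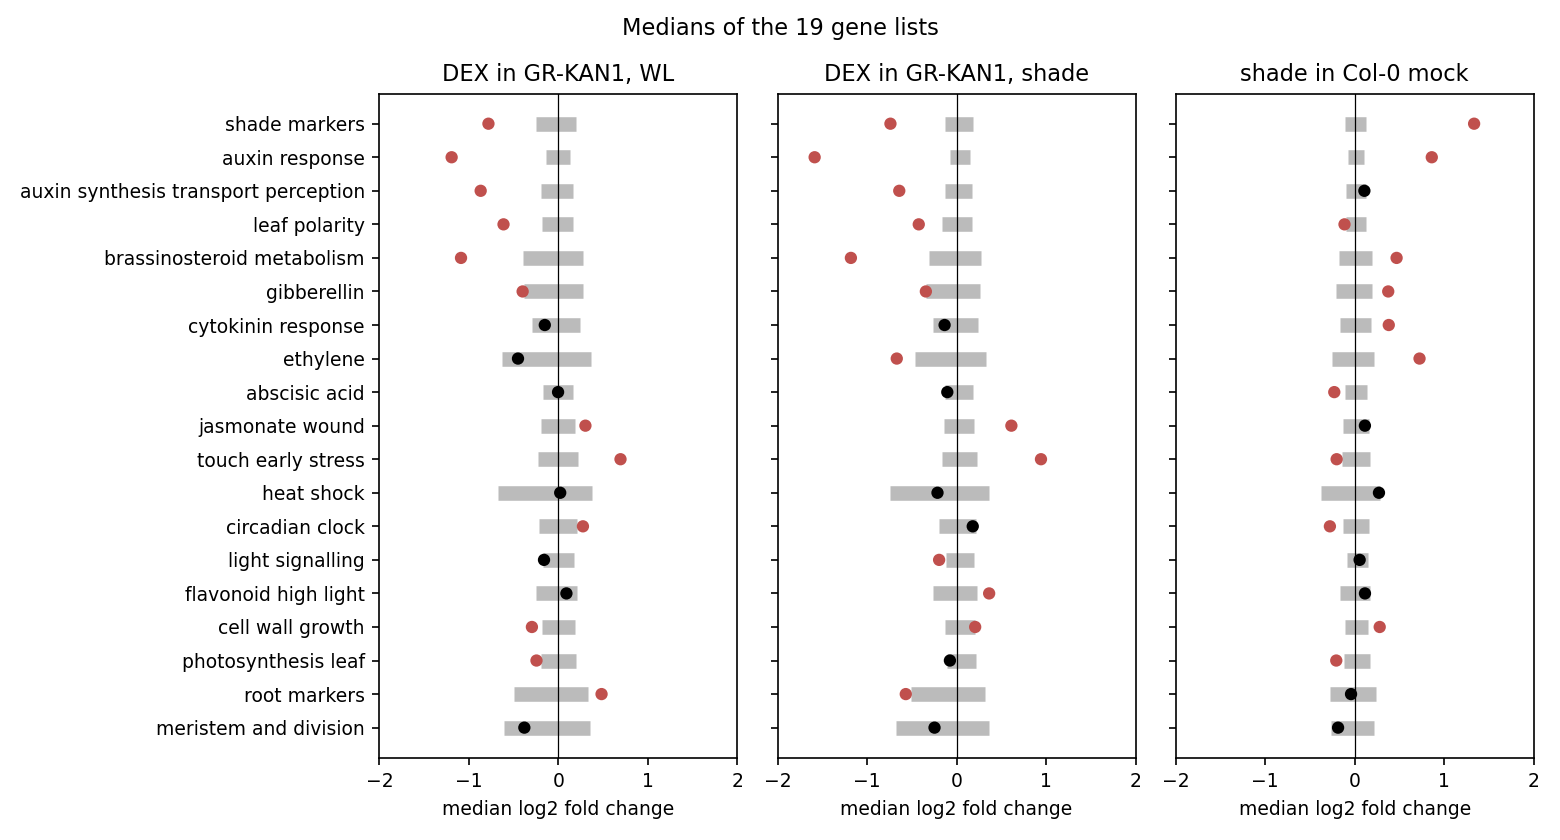
Median log2 fold change of each of the 19 lists fixed beforehand (points) in the DEX responses of GR-KAN1 in WL and in shade and in the shade response of mock-treated Col-0. Grey bars span the central 95% of 10000 random lists matched on expression; the auxin response median was -1.19 and -1.59 with DEX and 0.86 with shade.

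DEX in GR-KAN1 in shade asked the same question under the condition of the series title. Auxin response genes fell again, 19 of 28 tested with 0 higher and 9 not passing (25 lower adjusted over the list alone; median -1.59). The authors' deposited table gave log2 -3.26 for SAUR15, -2.63 for IAA6, -2.34 for IAA29 and -2.15 for IAA14. In the list of auxin synthesis, transport and perception 8 of 20 fell, 0 rose and 12 did not pass (11 lower and 2 higher adjusted over the list alone; median -0.64). YUC5, YUC8, YUC2 and YUC6 fell by 3.95, 3.58, 3.12 and 2.56 on the log2 scale in the authors' deposited table, YUC8 from 11.7 to 0.982 FPKM. With pseudocount 1 the log2 fold changes of YUC5, YUC6 and IAA6 in the DEX response of GR-KAN1 in shade were -2.33, -1.11 and -1.62. All 6 tested genes of brassinosteroid metabolism fell, also adjusted over the list alone (median -1.18). ROT3, BAS1, DWF4 and SOB7 among them were at log2 -1.64, -1.40, -1.23 and -1.13 in the authors' deposited table.

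Of 19309 genes tested in shade, 507 rose and 1075 fell with DEX in GR-KAN1. Within the limits of a symbol, 1 FPKM in both groups and no call with DEX in Col-0 in shade, the largest rises in the authors' deposited table were BHLH137 again, the calmodulin-like gene CML30 (log2 2.98), the transcription factors WRKY30 (2.93) and NAC036 (2.52), the ubiquitin ligase ATL80 (2.49) and PSK2 (2.38), a precursor of the peptide hormone phytosulfokine. KDR (AT1G26945), a small helix-loop-helix protein known to promote cell elongation, had the largest fall within these limits, from 41.9 to 1.19 FPKM in the authors' deposited table (log2 -5.13). BEE1, OPT1, MAKR6, PYL6 and DEAR2 followed within them in the authors' deposited table at -3.90, -3.73, -3.71, -3.51 and -3.45.

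Shade markers had 6 of 17 lower, 1 higher and 10 not passing in this comparison (9 and 1 adjusted over the list alone; median -0.74), with HAT2 at 97.1 FPKM under mock and 24.2 FPKM under DEX in the authors' deposited table. ATHB2, an HD-Zip II marker of shade looked up after its rise in WL, read 49.7 and 67.6 FPKM there in the authors' deposited table and was not called. Leaf polarity genes had 3 of 20 lower and 17 not passing (8 lower adjusted over the list alone; median -0.42), namely KAN3, ATHB8 and YAB5 at log2 -2.12, -1.31 and -1.13 in the authors' deposited table. The gibberellin list had 3 of 10 lower (4 adjusted over the list alone; median -0.34), with GA20OX1 at log2 -2.90 in the authors' deposited table. The ethylene list had 3 of 7 lower (4 lower and 1 higher adjusted over the list alone; median -0.67). The ACC synthase genes ACS4 and ACS8 in it were at log2 -4.15 and -3.41 in the authors' deposited table, ACS4 from 3.51 to 0.197 FPKM. With pseudocount 1 the log2 fold changes of ACS4, KAN3 and GA20OX1 in the DEX response of GR-KAN1 in shade were -1.91, -1.26 and -1.91. Abscisic acid genes had 5 of 17 lower and 1 higher (5 and 1 adjusted over the list alone; median -0.10). Light signalling genes had PKS1 and PIF7 lower again, 2 of 13 (3 lower and 1 higher adjusted over the list alone; median -0.20).

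Rises in shade came from touch and early stress genes, 3 of 8 (6 adjusted over the list alone; median 0.94), and from jasmonate and wounding genes, 4 of 13 with 1 lower (6 and 1 adjusted over the list alone; median 0.61). ZAT10 and TCH4 rose by 1.73 and 1.25 on the log2 scale in the authors' deposited table. JAZ7 and LOX3 rose by 1.79 and 1.18 there and JAZ6 fell by 2.04 in the authors' deposited table; JAZ genes encode repressors of the jasmonate response. The cell wall growth list had 2 of 11 lower and 1 higher, the same counts adjusted over the list alone, and its median (0.21) and mean (-0.31) differed in sign. The flavonoid list had 1 of 10 higher (1 adjusted over the list alone; median 0.36), and the root marker list had 1 of 8 lower (2 lower and 1 higher adjusted over the list alone; median -0.57). Cuffdiff called 0 of 8 cytokinin response, 0 of 6 heat shock, 0 of 11 clock, 0 of 9 photosynthesis and 0 of 6 meristem genes, with 4, 1, 4, 0 and 1 at an unadjusted deposited p under 0.05. Adjusted over the list alone, the cytokinin list had 2 higher and 2 lower, and its median (-0.13) and mean (0.07) differed in sign. On the same basis the meristem list had 1 lower (median -0.25), and the heat shock, clock and photosynthesis lists had 0 (medians -0.21, 0.18 and -0.07).

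The DEX responses of GR-KAN1 in WL and in shade, which share no library, overlapped widely. Of the genes tested in both, 759 fell in both lights where independent lists would share 60.2, and 341 rose in both where 15.9 would. Of 1671 genes called in WL and tested in shade, 1596 (95.5%) had the same sign there. Across 18546 genes, which are not independent replicates, Pearson's r was 0.75 and Spearman's rho 0.67. A further 14 genes rose in WL and fell in shade (33.7 for independent lists; Fisher's exact p = 0.000134), and 0 fell in WL and rose in shade (28.4 for independent lists; Fisher's exact p = 2.24e-13). Among the 14, named after their values were seen, are AIR1 and AGP30, with 36.6 and 91.5 FPKM for AIR1 in WL (mock and DEX) and 92.6 and 16.5 FPKM in shade in the authors' deposited table.

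**Figure D3:**
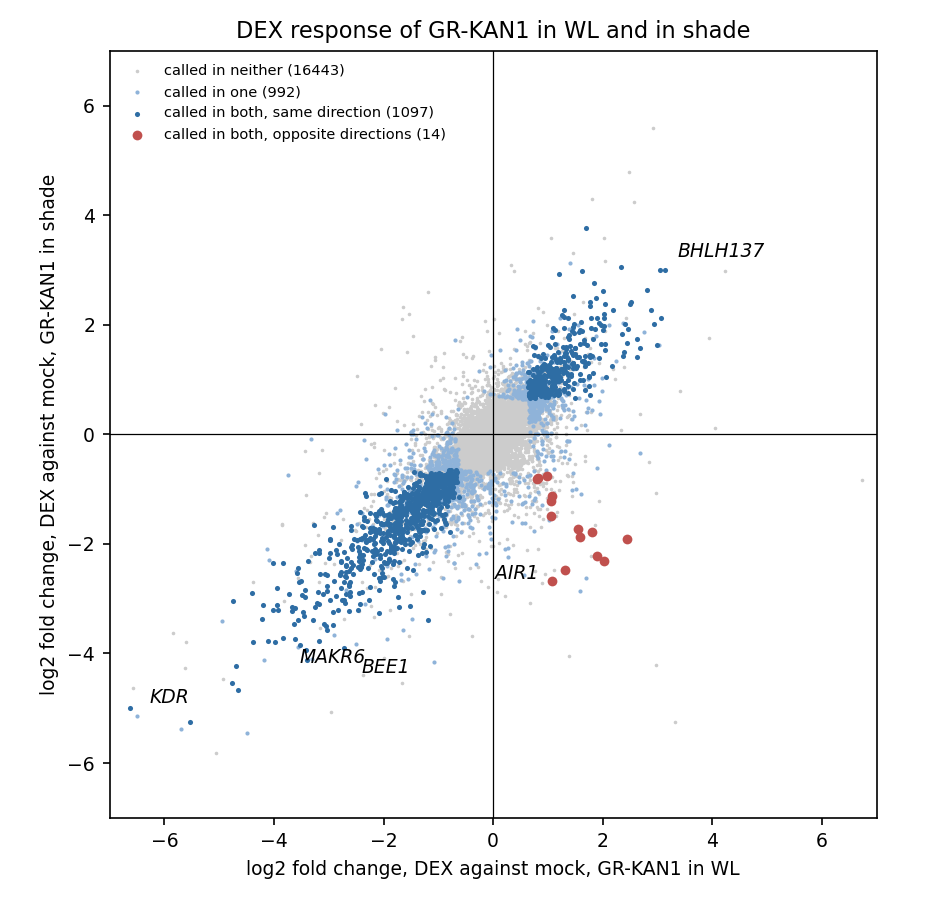
Log2 fold change of DEX against mock in GR-KAN1 in WL (x axis) and in shade (y axis) for 18546 genes with at least 1 FPKM, 1 point per gene. Dark blue points are the 1097 genes plotted that were called in both lights in the same direction, and red points the 14 called in opposite directions.

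The difference of the 2 DEX responses (shade minus WL) was called for 78 of 19037 genes, 19 above and 59 below 0. It is also the test of whether DEX altered the shade response of GR-KAN1. AIR1 (AT4G12550) and its neighbour AT4G12545 had differences of -3.80 ± 0.31 and -3.75 ± 0.34 (SE). Taken from the deposited p, the standard errors were 0.69 and 0.72. The deposited p of AIR1 was at its floor of 5e-05 in both lights, and that of AT4G12545 in shade. The values 0.69 and 0.72 are therefore upper bounds and not measured errors. The other 4 genes with the smallest p were RPL32, PSAJ, AT5G04790 and AT1G67785, at 2.06, 1.39, 2.38 and 0.75. In neither light was the DEX response of these 4 called, and their implied standard errors ran from 0.0147 to 0.119. With the standard error from the deposited p, the DEX response difference shade minus WL in GR-KAN1 was called for 38 genes, a count limited by that floor. No member of the auxin response list was called (0 of 28; 6 at an unadjusted p under 0.05, 2 below 0 adjusted over the list alone; median -0.18). Nor was any of the shade markers (0 of 15; 1 at an unadjusted p under 0.05, 0 adjusted over the list alone; median -0.47). The root marker list lay at a median of -0.92 for this difference, below all 10000 random lists, with 1 of 6 called (2 below 0 adjusted over the list alone). The medians of the auxin response and shade marker lists were below 0 too, so the root markers were not alone in that direction. AIR1 and AGP30 are themselves known mainly from roots.

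DEX in Col-0 served as the control for the hormone itself. In WL 18 genes rose and 49 fell. Among genes with a symbol and at least 1 FPKM in both groups, the largest rises in the authors' deposited table were ICL (an enzyme of the glyoxylate cycle; 8.59-fold), GSTF14 (log2 2.01) and NAS2 (1.65), and the largest falls ERF105 (-1.92), OXS3 (-1.90) and CBF2 (-1.88). In shade 144 rose and 101 fell. Under the same limits GSTF14 and NAS2 again (log2 2.81 and 2.42) and CYP71A12 (2.40) were at the top and the iron deficiency regulators bHLH38 and BHLH100 (-1.56 and -1.45) and ATPMEPCRB (-1.40) at the other end in the authors' deposited table. Auxin response genes had 0 of 27 called in WL (0 at an unadjusted deposited p under 0.05 and 0 adjusted over the list alone; median 0.10) and 1 of 28 higher in shade (2 adjusted over the list alone; median 0.15). With a normal p from the test statistic, the DEX response of Col-0 in WL had 42 genes called, 25 higher and 17 lower, which turns the split, and the DEX response of Col-0 in shade 122. Of 49 genes lower in WL, 43 were also called lower in mock-treated GR-KAN1 than in the same mock-treated Col-0 libraries.

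Set against that in Col-0, the DEX response of GR-KAN1 was called different for 765 genes in WL, 168 above and 597 below, and for 970 genes in shade, 214 above and 756 below. Auxin response genes were below Col-0 for 10 of 27 in WL and 23 of 28 in shade (16 and 23 adjusted over the list alone). Shade markers were below Col-0 for 6 of 14 in WL, with 1 above, and for 7 of 17 in shade (6 and 1, and 9 adjusted over the list alone). With DEX in Col-0 in shade 2 of 17 shade markers rose and 0 fell (3 higher adjusted over the list alone; median 0.25). The gap in shade therefore takes in a rise in Col-0 as well. By the naming rule KDR differed by -5.08 ± 0.51 (SE) in shade, where its own change in Col-0 was -0.05 in the authors' deposited table. AT1G26250 and AT5G42530 differed there by -4.47 ± 0.45 and -3.39 ± 0.34 (SE), and both fell in GR-KAN1 and rose in Col-0. PSAJ, PSBM and MIR157c completed the shade set, called with DEX in neither genotype. The genes with the smallest p in WL were PSAJ, AT2G40205, U1.5, AT5G04790, RPL32 and AT1G67785, none of them called with DEX in either genotype in WL, with implied standard errors of 0.00350 to 0.114. With the standard error from the deposited p they were instead ZAT10 (2.67), AT3G15450 (2.53), BT2 (2.90), AT4G32480 (2.75), GSTF14 (-5.75) and ASN1 (1.79). This order is shaped by the floor of the deposited p and is not a better ranking. Under that floor, genes with opposite changes in the 2 genotypes come first, and a gene changed in GR-KAN1 alone cannot. In WL 9 genes that rose in GR-KAN1 fell in Col-0 (1.52 for independent lists) and 3 that fell rose in Col-0 (0.903), while 2 rose in both (0.496) and 4 fell in both (2.77). In shade 40 genes that fell in GR-KAN1 rose in Col-0 (7.82 for independent lists) and 26 that rose fell in Col-0 (2.66 for independent lists), while 3 rose in both (3.66) and 8 fell in both (5.68). Across genes, the DEX responses of the 2 genotypes had a Pearson's r of -0.03 in WL (18505 genes) and -0.18 in shade (18554 genes).

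Shade in mock-treated Col-0 gave the wild-type shade response, and its markers rose: 12 of 17 were higher, 0 lower and 5 not passing (14 higher adjusted over the list alone; median 1.33, above all 10000 random lists). YUC9 read 0.485 and 11.5 FPKM in WL and shade in the authors' deposited table, and ATHB2 (AT4G16780) 5.48 and 39.7 FPKM. ATHB4, another HD-Zip II gene, and YUC8 rose by 3.83 and 2.25 on the log2 scale in the authors' deposited table. Auxin response genes had 11 of 28 higher, 0 lower and 17 not passing (16 higher adjusted over the list alone; median 0.86), among them SAUR19, IAA29, SAUR22 and SAUR23. Their log2 changes were 2.04, 2.04, 1.98 and 1.49 in the authors' deposited table; neighbouring SAUR genes are near-identical and can share reads. In the auxin synthesis list 5 of 20 rose and 0 fell (6 higher adjusted over the list alone; median 0.11), YUC5 and YUC2 among them at log2 2.18 and 1.61 in the authors' deposited table. TAA1 and PIF7, looked up after their fall with DEX was seen, at 0.14 and -0.07 in the authors' deposited table, were not called.

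Of 19250 genes tested for shade in Col-0, 159 rose and 241 fell. BHLH87 (log2 3.02), the ACC synthase gene ACS8 (2.31), SAUR28 (2.27) and ICL (2.26) were the other large rises by the naming rule in the authors' deposited table. The largest falls by that rule, in the authors' deposited table, were the B-box gene BBX31 (-2.92), the abscisic acid hydroxylase CYP707A2 (-2.13), the cold response gene CBF2 (-2.05), ERF105 (-2.01), the clock gene PRR9 (-1.87) and the glucosyltransferase DOGT1 (-1.86). CBF2 and ERF105 also fell with DEX in Col-0 in WL, against the same libraries, and in shade in mock-treated GR-KAN1 the authors' deposited table gave them -0.31 and 0.13, not called. The 49 genes lower with DEX in Col-0 in WL, chosen against the same mock-treated group, had a median of -0.20 with shade in mock-treated Col-0 and 1.13 in mock-treated GR-KAN1.

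Smaller moves with shade in Col-0 were 2 of 7 brassinosteroid genes higher (3 adjusted over the list alone; median 0.47), BAS1 and DWF4, and 1 of 8 gibberellin genes higher, GA3OX1 (1 adjusted over the list alone; median 0.37). There were also 3 of 8 cytokinin response genes higher, ARR7, ARR6 and ARR4 (3 adjusted over the list alone; median 0.38). The cell wall growth list had 2 of 11 higher, XTH33 and XTH15 (4 higher and 3 lower adjusted over the list alone; median 0.28). The ethylene list had 1 of 6 higher and 1 lower (2 and 1 adjusted over the list alone; median 0.72). The abscisic acid list had 1 of 15 higher and 2 lower, the same adjusted over the list alone (median -0.23), and the touch list 2 of 8 lower, ZAT10 and ZAT12 (2 lower and 2 higher adjusted over the list alone; median -0.20). In the other shade comparisons the touch list had 0 lower, with medians of 0.20 (Col-0 DEX), 0.09 (GR-KAN1 mock) and 0.22 (GR-KAN1 DEX). Against the same mock-treated Col-0 WL group its median was also low with DEX in Col-0 (-0.28) and in mock-treated GR-KAN1 (-0.32). HYH and SPA1 fell, 2 of 13 light signalling genes (2 adjusted over the list alone), with a median of 0.05 and a mean of -0.11 of opposite sign. VSP2 fell in the jasmonate list, 1 of 13 (2 adjusted over the list alone), whose median (0.11) and mean (-0.02) differed in sign. PRR9 fell in the clock list, 1 of 11 (1 adjusted over the list alone; median -0.28), and ELIP2 rose in the flavonoid list, 1 of 10 (1 higher and 1 lower adjusted over the list alone; median 0.11). Cuffdiff called 0 of 20 leaf polarity, 0 of 6 heat shock, 0 of 9 photosynthesis, 0 of 8 root marker and 0 of 6 meristem genes, with 1, 0, 0, 0 and 1 at an unadjusted deposited p under 0.05. All were at 0 adjusted over the list alone, and their medians were -0.11, 0.27, -0.21, -0.04 and -0.19.

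The other 3 shade comparisons called 702 genes in Col-0 with DEX (287 higher, 415 lower), 658 in GR-KAN1 with mock (290 and 368) and 440 in GR-KAN1 with DEX (165 and 275). Shade markers rose in each, 14, 13 and 10 of 17 (15, 15 and 14 adjusted over the list alone), with medians of 1.76, 1.60 and 1.40. Auxin response genes rose for 12 of 28, 10 of 28 and 4 of 25, the last with 1 lower (19 higher and 1 lower, 15 and 1, and 9 and 1 adjusted over the list alone), with medians of 0.95, 0.67 and 0.33. Between mock-treated Col-0 and mock-treated GR-KAN1, which share no library, 101 genes rose in shade in both (2.34 for independent lists) and 161 fell in both (4.62 for independent lists). There 94.5% of the genes called in Col-0 had the same sign in GR-KAN1.

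**Figure D4:**
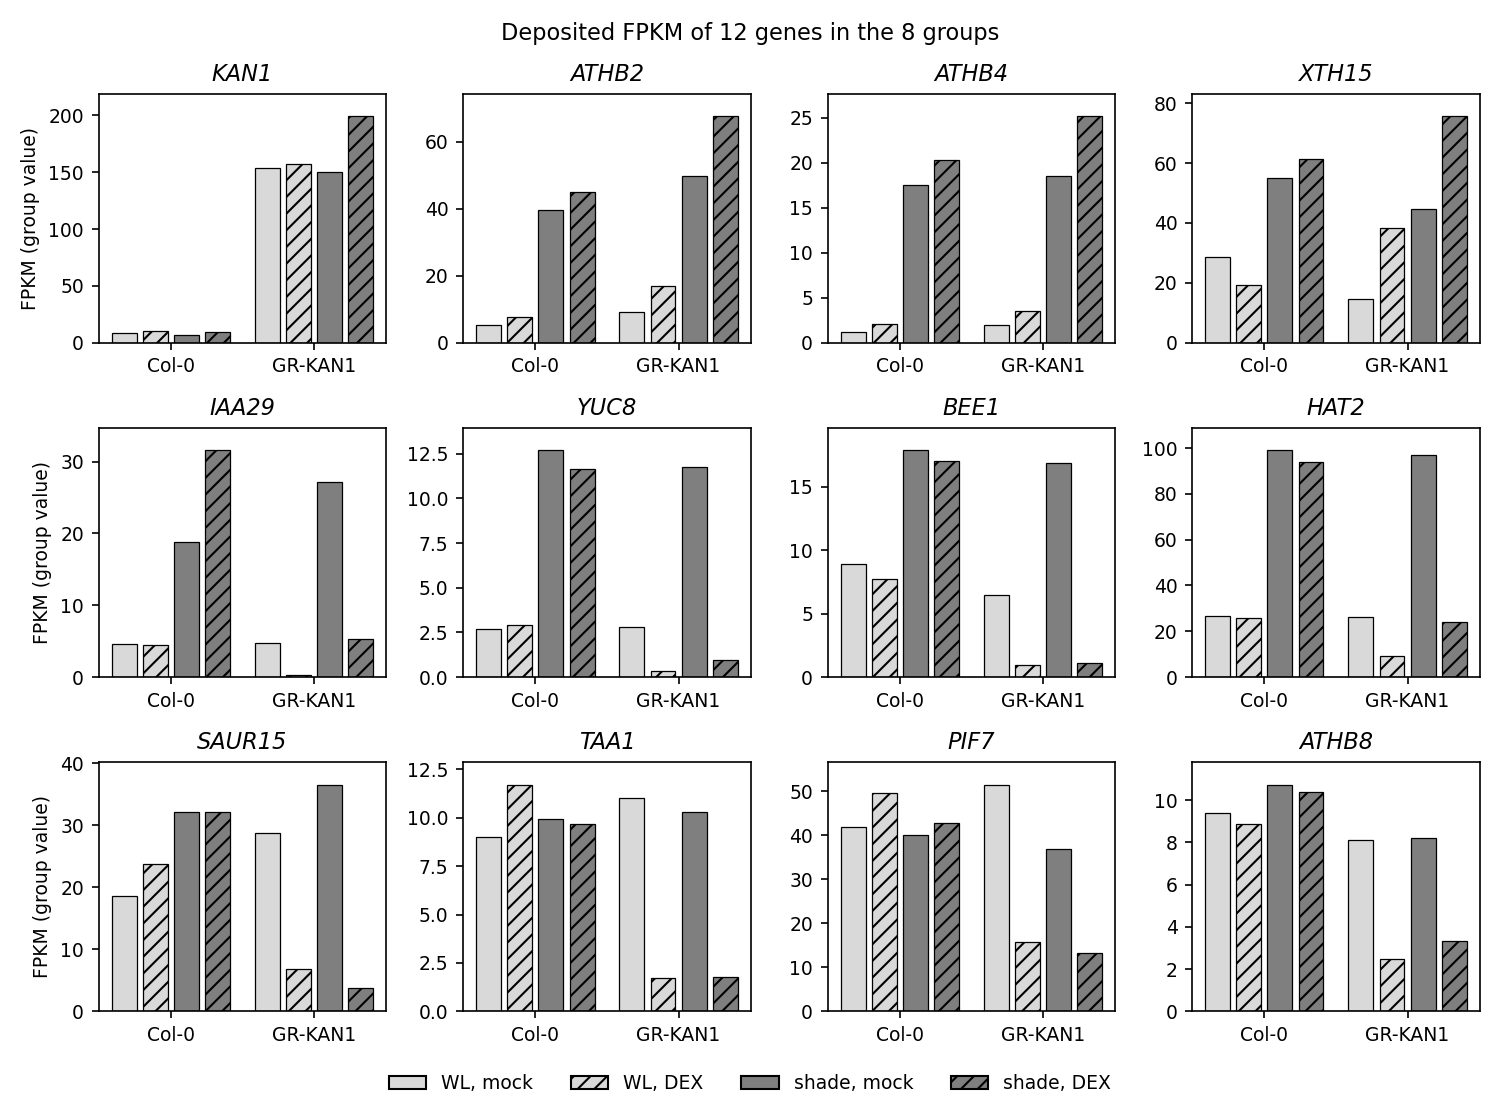
Deposited FPKM of 12 genes in the 8 groups, with Col-0 at the left and GR-KAN1 at the right of each panel, WL light grey, shade dark grey and DEX hatched; bars are 1 value per group with no error. YUC8 rose with shade in Col-0 from 2.66 to 12.7 FPKM and stood at 0.342 and 0.982 FPKM in GR-KAN1 with DEX.

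The KAN1 and shade responses met in both directions. Among genes tested for DEX in GR-KAN1 in WL and for shade in mock-treated Col-0, which share no library, 51 fell with DEX and rose in shade (8.73 for independent lists), 72 fell in both (13.6), 33 rose in both (4.84) and 25 rose with DEX and fell in shade (7.52). All 4 classes lay above these numbers, which are not matched on expression, so an excess alone does not show a link between the responses. With an absolute log2 fold change of 1 or more in both, the Overlap of KAN1 and shade calls fell to 27 (KAN1 lower, shade higher), 24 (KAN1 lower, shade lower), 6 (KAN1 higher, shade higher) and 12 (KAN1 higher, shade lower), so the balance of the 4 classes rests on the threshold. Across 18470 genes Pearson's r was 0.06 and Spearman's rho 0.12. For DEX in GR-KAN1 in shade beside shade in DEX-treated Col-0, which also share no library, 127 genes fell with DEX and rose in shade (15.8 for independent lists). In that pairing 76 did the reverse (10.9), 43 fell in both (23.2) and 7 rose in both (7.41).

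A narrower set took the 96 genes that rose with shade in Col-0 both under mock and under DEX. Of them 33 (34.4%) fell with DEX in GR-KAN1 in both lights where independent lists, not matched on expression, would give 3.88 (Fisher's exact p = 2.64e-22). XTH15 and AT5G66080, 2 of the 96, rose in both lights (1.74 for independent lists; Fisher's exact p = 0.694). Of the 141 genes lower in shade in both Col-0 comparisons, 21 fell with DEX in GR-KAN1 in both lights (5.69 for independent lists; Fisher's exact p = 2.34e-07) and 14 rose (2.56; p = 2.9e-07 by the same test). The 2 DEX comparisons and the 2 shade comparisons behind these sets share no library with each other.

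Named among the 33 after their values were seen, IAA29, YUC8, HAT2, HAT1, PIN3, IAA2, BEE1, DWF4 and KAT1 rose with shade and fell with DEX. In the authors' deposited table IAA29 (chromosome 4, 15583387 to 15584769 on TAIR10) went from 4.59 to 18.9 FPKM with shade in mock-treated Col-0, and its DEX values in GR-KAN1 were 0.291 FPKM in WL and 5.35 FPKM in shade. HAT2 went from 26.9 to 99.0 FPKM with shade in Col-0 and stood at 24.2 FPKM in shaded GR-KAN1 with DEX in the authors' deposited table. IAA2, at 108 and 299 FPKM in mock-treated Col-0 in WL and shade, stood at 51.0 and 109 FPKM in GR-KAN1 with DEX in the authors' deposited table, where its shade rise was called as well (log2 1.09).

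GR-KAN1 against Col-0 under mock asked what the line changes without inducer. KAN1 was 1 of 95 genes higher in WL and of 82 higher in shade, and 141 and 64 genes were lower. By the naming rule, WL had GSTF14 (log2 2.46) and the nicotianamine synthase NAS2 (2.18) higher and the threonine aldolase THA1 (-2.77), BCAT-2 (-2.43) and MIOX4 (-2.25) lower in the authors' deposited table. GSTF14 and NAS2 also rose with DEX in Col-0 in WL (2.01 and 1.65), against the same mock-treated Col-0 group. They rose with DEX in Col-0 in shade as well (2.81 and 2.42), against the mock-treated Col-0 group there. These rises came with another treatment and do not show whether the line itself raised GSTF14 and NAS2. With DEX in GR-KAN1 in WL the log2 change of GSTF14 was -3.74 in the authors' deposited table. Shade had the defensin PDF1.2 (3.42) and AGP30 (2.07) higher and MIOX4 (-2.25), THA1 (-2.11) and ICL (-2.01) lower in the authors' deposited table. Cuffdiff called 0 of 28 auxin response genes in either light (2 at an unadjusted deposited p under 0.05 in each, 0 adjusted over the list alone; medians 0.18 and 0.15). With Benjamini-Hochberg within the comparison, GR-KAN1 against Col-0 mock in WL had 138 genes called and GR-KAN1 against Col-0 mock in shade 72.

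The shade response of mock-treated GR-KAN1 differed from that of mock-treated Col-0 for 51 of 19024 genes, 23 above and 28 below. PSBA, the plastid gene of a photosystem II core protein, rose with shade in Col-0 and fell in GR-KAN1 (difference -2.86 ± 0.32, SE). The authors' deposited table gave it 73.9 and 240 FPKM in Col-0 in WL and shade and 233 and 104 FPKM in GR-KAN1. The other genes with the smallest p were AT1G15405 (-2.98 ± 0.26, SE), U1.5 (-3.13), AT2G40205 (-0.51), MIR157c (0.92) and AT1G67785 (-0.81), mostly short or non-coding transcripts. The median over 47 plastid transcripts was 0.55 with shade in Col-0 and -0.53 in GR-KAN1. Of the shade markers 0 of 17 differed (0 at an unadjusted p under 0.05, 0 adjusted over the list alone; median 0.11) and of the auxin response genes 0 of 28 (1 at an unadjusted p under 0.05, 0 adjusted over the list alone; median -0.05). Without organelle genes and genes that are not protein-coding, the Shade response difference GR-KAN1 minus Col-0 mock was called for 30 genes, 21 above and 9 below, which turns the split. With the standard error from the deposited p, which has a floor, it was called for 18.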

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

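Both tests on plastid transcripts and the test of dexamethasone in Col-0 were written after their results had been seen, and 1 further test, on the mock-treated Col-0 libraries in WL, was scored anew after its values were seen and is void. A range in brackets after a median in this section comes from 2000 bootstrap draws, in which the genes of the set were resampled. It describes the spread between genes, which can be regulated together, within the same group values. It does not measure the spread between libraries or plants, so it is not an error of a difference between groups.

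The same contrast differed between groups by a test of the difference itself in 4 places. The DEX response of GR-KAN1 was called different from that of Col-0 for 765 genes in WL and 970 genes in shade. Such a difference also takes in any shift of a Col-0 group, for example of the mock-treated group in WL or the DEX-treated group in shade. Neither count alone therefore says on how many genes DEX acts differently. In shade 801 of the 970 genes had log2 changes of opposite sign in GR-KAN1 and Col-0, and in WL 538 of the 765. Choosing genes by a large difference itself favours opposite signs, so these counts do not show that Col-0 moved the other way. Among all genes called with DEX in GR-KAN1 and tested in Col-0, 51.1% in WL and 34.8% in shade had the same sign in Col-0. With DEX in Col-0 in shade the iron list had a median of -0.90 and the added root list 0.52. Whether these medians reflect DEX or a shift of a Col-0 group was not tested. DEX in GR-KAN1 differed between shade and WL for 78 genes. Shade differed between mock-treated GR-KAN1 and mock-treated Col-0 for 51 genes.

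For DEX in GR-KAN1, shade minus WL, the genes with the smallest p differed by 2.06 (RPL32), 1.39 (PSAJ), 2.38 (AT5G04790), -3.80 (AIR1), -3.75 (AT4G12545) and 0.75 (AT1G67785). AIR1 and AT4G12545 were called with opposite signs in the 2 lights, and the other 4 were called in neither. For shade, GR-KAN1 minus Col-0 under mock, they differed by -0.51 (AT2G40205), -3.13 (U1.5), -2.98 (AT1G15405), 0.92 (MIR157c), -0.81 (AT1G67785) and -2.86 (PSBA). Of these 6, PSBA was called in both genotypes with opposite signs. In the authors' Cuffdiff run the deposited p of RPL32, PSAJ, AT5G04790 and AT1G67785 with DEX ran from 0.0571 to 0.827 over both lights, and that of AT2G40205, U1.5 and MIR157c with shade from 0.184 to 0.883 over both genotypes. The differences of these genes rest on standard errors that the deposited statistic makes very small, and with the standard error from the deposited p none of them was among the 6 genes with the smallest p. The floor of the deposited p also shapes that second order.

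A different share of root tissue was weighed for the 14 genes that rose with DEX in WL and fell in shade in GR-KAN1, AIR1 and AGP30 among them. Over 20 other root genes, chosen after the data were seen, the median difference of the DEX responses was -0.97 (-1.24 to -0.60), in the same direction as the median of the 14 genes, -3.36 (-3.78 to -2.21). The prediction, written before, asked for -1.68 or lower and was not met. However, the 14 genes were chosen for opposite calls in these same comparisons, so their median is extreme by selection. The test therefore cannot decide whether a different share of root is a part or the whole of the pattern. The added root list also lay at 0.65 in mock-treated GR-KAN1 against Col-0 in shade and at 0.52 with DEX in Col-0 in shade, so it varied between groups without induced KAN1. An effect of light on what induced KAN1 does in roots, which the design allows, was not tested.

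RNA without poly(A) tails left in some libraries was weighed for the plastid transcripts, 47 genes with medians of 0.55 with shade in Col-0, -0.53 with shade in GR-KAN1, 0.61 in GR-KAN1 against Col-0 in WL and -0.72 in shade, all under mock. The mitochondrial median over 12 genes had the same sign in 4 of the 4 comparisons (0.96, -0.44, 0.59 and -1.01), which the explanation needs. However, 3 of the 4 mitochondrial ranges, taken over genes, include 0. The comparisons also form a loop over the same 4 groups, so these are not 4 separate matches. A nuclear ribosomal RNA gene, AT3G41768, read 225 and 609 FPKM in mock-treated Col-0 in WL and shade and 799 and 219 FPKM in GR-KAN1 in the authors' deposited table. With DEX in GR-KAN1 in WL it was called lower (log2 -1.75). So were PSAA (-1.97), RBCL (-1.49), PSBA (-1.12) and the mitochondrial RRN26 (-0.98), while RRN18 (-0.66) was not called. These falls are part of the main DEX comparison in WL. None of these transcripts was called with DEX in GR-KAN1 in shade. Shade acting alike in both genotypes, with nothing else different, would need the same sign. The plastid median in GR-KAN1 was -0.53 (-0.92 to -0.28) against 0.55 (0.30 to 1.04) in Col-0, which argues against it as the whole cause. RNA without poly(A) tails, if left in some libraries, could hide a shared effect of shade, so these signs cannot exclude one. A true difference of the shade response between the genotypes was not tested apart from these.

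Dexamethasone itself and a mock-treated Col-0 WL group that stands apart were weighed for the 49 genes lower with DEX in Col-0 in WL. In shade, with other libraries, their median with DEX in Col-0 was 0.03 (-0.01 to 0.12), which argues against the hormone lowering them in both lights. Of the 49, 87.8% (43 genes) were also lower in mock-treated GR-KAN1 than in the same Col-0 group, where no dexamethasone was given. Simulated unchanged groups that share a control gave 4.62%. That simulation used normal noise and a cut at the median statistic of the 49 genes, not the deposited q, so the percentages are at unlike thresholds. The overlap also uses the group by which the genes were chosen, so it alone does not decide about the hormone in WL. For a Col-0 group that stands apart, the median with shade in mock-treated Col-0 minus that in mock-treated GR-KAN1 was -1.32 (-0.20 against 1.13), but per gene this difference is made of the same values as the comparison just given, on genes chosen for their level in that Col-0 group, so the test is void and leaves open whether that group stands apart; the median in mock-treated GR-KAN1 against Col-0 in shade, without that group, was 0.08 (0.02 to 0.18). As first written the prediction asked for a median further from 0 in mock-treated Col-0, which was not met, and the test was then scored on the difference. With shade the 49 genes also had medians of 0.93 (0.59 to 1.15) in DEX-treated Col-0 and 0.65 (0.46 to 0.90) in DEX-treated GR-KAN1. Those comparisons do not use the mock-treated Col-0 WL group, but the choice of genes by their level in it still keeps the question open. No biological explanation was tested.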

How the results depend on the processing

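DEX in GR-KAN1 kept its counts within 1.5 times under every alternative run, from 1122 to 1902 genes for the DEX response of GR-KAN1 in WL and from 1076 to 1778 for the DEX response of GR-KAN1 in shade. Without genes called in the same direction in Col-0 DEX they were 1668 and 1571. Of the counts, overlaps and the correlation 73 results stayed the same and 45 moved. Of 190 list medians centred on the median of all genes all 190 stayed the same; with no FPKM minimum 177 did, 9 were weaker, 3 stronger and 1 reversed; with pseudocount 1 and pseudocount 0.1, 184 and 188 did. Of 171 named gene values 123 stayed within the limit with pseudocount 1 and all with pseudocount 0.1, and 0 reversed. Centring moved the percent lower among called genes by at most 3.97 points. Leave-one-out and a replicate block were not run. No paired analysis was possible because the table holds 1 value per group and none per library, and the 2 libraries of a group are technical replicates. Depth is unknown, so no limit on low counts can be given. In the values below the smaller counts follow from stricter thresholds where the setting names one; otherwise the cause was not tested.

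With Benjamini-Hochberg within the comparison the DEX response of Col-0 in WL had 29 genes and the DEX response of Col-0 in shade 136, and GR-KAN1 against Col-0 mock in WL 138 and GR-KAN1 against Col-0 mock in shade 72. With a q threshold of 0.01 the DEX response of Col-0 in WL had 40 genes and the DEX response of Col-0 in shade 136, the Shade response of Col-0 mock 246, the Shade response of GR-KAN1 mock 425 and the Shade response of GR-KAN1 DEX 265, and GR-KAN1 against Col-0 mock in WL 138 and GR-KAN1 against Col-0 mock in shade 87. With an absolute log2 fold change of 1 or more as well the same comparisons had 36 and 129, 195, 367 and 220, and 105 and 84, and the Shade response of Col-0 DEX 371. With a normal p from the test statistic the DEX response of Col-0 in WL had 42 (25 higher and 17 lower, against 18 and 49) and the DEX response of Col-0 in shade 122, the Shade response of Col-0 mock 207, the Shade response of GR-KAN1 mock 438 and the Shade response of GR-KAN1 DEX 258, and GR-KAN1 against Col-0 mock in WL 118. With a normal p, log2 fold changes centred on their median, the DEX response of Col-0 in WL had 42 (24 higher and 18 lower) and the DEX response of Col-0 in shade 123, the Shade response of Col-0 mock 209, the Shade response of Col-0 DEX 463, the Shade response of GR-KAN1 mock 425 and the Shade response of GR-KAN1 DEX 265, and GR-KAN1 against Col-0 mock in WL 126.

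With a threshold of 0.01 the DEX response difference GR-KAN1 minus Col-0 in WL had 487 genes and the DEX response difference GR-KAN1 minus Col-0 in shade 630, and the DEX response difference shade minus WL in GR-KAN1 50. The standard error from the deposited p, chosen after seeing the data, is kept large for genes at the floor of that p. It gave 38 for the DEX response difference shade minus WL in GR-KAN1 and 18 for the Shade response difference GR-KAN1 minus Col-0 mock. The latter, without organelle genes and genes that are not protein-coding, an alternative also chosen after seeing the data, had 30 (21 above and 9 below, against 23 and 28). With an absolute log2 fold change of 1 or more in both, the Overlap of KAN1 and shade calls was 6 (KAN1 higher, shade higher), 12 (KAN1 higher, shade lower), 27 (KAN1 lower, shade higher) and 24 (KAN1 lower, shade lower), and the Overlap of KAN1 calls in WL and shade 169 (KAN1 higher, KAN1 in shade higher). The Correlation of KAN1 and shade responses was 0.0820 with a 5 FPKM minimum and 0.0185 over genes called in either comparison, against 0.0553. The median of ethylene, Shade response of GR-KAN1 DEX, reversed with no FPKM minimum, to -0.0731 from 0.364.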

Other observations

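Gene lists added after the data were seen hold further groups. Of 9 sugar starvation genes 5 rose with shade in mock-treated Col-0 (9 adjusted over the list alone; median 0.90), 8 in DEX-treated Col-0, 8 in mock-treated GR-KAN1 and 7 in DEX-treated GR-KAN1 (8, 8 and 7 adjusted over the list alone; medians 1.60, 1.92 and 1.23). In WL 7 of the 9 fell with DEX in Col-0 and 8 were lower in mock-treated GR-KAN1 than in Col-0 (7 and 9 adjusted over the list alone; medians -0.86 and -1.29), both against mock-treated Col-0, and with DEX in GR-KAN1 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.58). ASN1, an asparagine synthetase gene induced by darkness and starvation, read 51.7, 30.1, 12.9 and 26.0 FPKM in WL in the order mock and DEX in Col-0, then mock and DEX in GR-KAN1, and 118, 121, 76.5 and 100 FPKM in shade, in the authors' deposited table. Phosphate starvation genes fell with shade in DEX-treated GR-KAN1, 6 of 11 (8 adjusted over the list alone; median -2.42), and 4 of 10 in DEX-treated Col-0 (6 adjusted over the list alone; median -1.08). Under mock 2 of 10 fell with shade in each genotype (2 lower in Col-0, and 3 lower and 1 higher in GR-KAN1, adjusted over the list alone; medians -0.41 and -0.30). With DEX in Col-0 in shade Cuffdiff called 0 of 10 (3 at an unadjusted deposited p under 0.05, 3 lower adjusted over the list alone; median -0.46). With DEX in GR-KAN1 the list had 2 higher and 2 lower of 11 in WL (5 and 2 adjusted over the list alone; median 0.63) and 2 lower of 10 in shade (4 adjusted over the list alone; median -0.86). SPX1, a sensor protein gene of phosphate status and 1 of the 2 that fell in WL, fell by 1.51 and 3.14 on the log2 scale with DEX in GR-KAN1 in WL and in shade, in the authors' deposited table. With shade in DEX-treated GR-KAN1 the root marker list and the added root list were low as well (medians -0.83 and -0.56). With shade in DEX-treated Col-0 the added root list went the other way (0.23).

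DEX-treated Col-0 in shade carried 2 other moves. Of 13 iron genes 7 fell and 3 rose with DEX there (7 and 4 adjusted over the list alone; median -0.90, mean -0.18), with bHLH38 and bHLH39, regulators of iron uptake, at log2 -1.56 and -1.33 and the ferritin genes FER1 and FER4 at 1.81 and 1.00 in the authors' deposited table. Seed storage genes stood higher there: the cruciferin gene CRA1 read 35.0 FPKM against 0.0969 to 1.70 FPKM in the other 7 groups in the authors' deposited table, and SESA1, CRU3 and OLEO1 read 52.6, 33.2 and 11.6 FPKM. With DEX in Col-0 in shade 2 of 10 seed storage genes were called higher, and with shade in DEX-treated Col-0 4 of 10 (3 and 5 adjusted over the list alone). Their fold changes are not given, since most members were near 0 FPKM in the other groups. In the added list of 25 root genes DEX in GR-KAN1 raised 2 of 22 tested in WL and in shade raised 2 and lowered 5 of 21 (2 higher and 1 lower, and 3 higher and 8 lower adjusted over the list alone; medians 0.31 and -0.59). With DEX in Col-0 in shade Cuffdiff called 0 of 22 of these root genes (9 at an unadjusted deposited p under 0.05, 3 higher adjusted over the list alone), and their median, 0.52, lay above those of all 10000 random lists.

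A hypothesis of the present work, with its prediction written before the test, was that genes lower with DEX in GR-KAN1 in both lights carry the KANADI binding motif VGAATAW near their start more often than unchanged genes. Within 500 bp upstream 57.9% of 755 such genes had a site, against a mean of 47.0% (43.4 to 50.3) in 1000 draws of matched genes from 16534 unchanged ones, an excess of 10.9 points. Of 19 other orders of the same core bases 0 had an excess as large; the largest was 10.1 points for VAGAATW, a word close to the motif, and 9 of the 19 were themselves above the central 95% of their random sets. The 337 genes higher in both lights had 43.0% against 47.2% (42.1 to 52.5). The test came out as predicted by a narrow margin. Several other words of the same bases were also more frequent, so the excess could come in part from the composition of these promoters, and binding was not measured here.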
